A study of Mus musculus with 75 samples.

How the data were processed

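The samples were CD4 effector T cells (CD4+CD25-) from spleen and lymph nodes of 9 mice, cultured with anti-CD3/CD28 beads, with beads and Tregs, with beads and HHT for 10 min, or without stimulation, per the labels. The Tregs came from mice that report Foxp3, a transcription factor of Tregs, with a fluorescent protein. In RiboTag (5 mice) RNA was taken before and after precipitation of the hemagglutinin-tagged ribosomes, and in SPEED (4 mice) from Input, polysomal and subpolysomal sucrose fractions. Libraries were made with a SMART-Seq v4 low input kit and NexteraXT, per the labels' protocols. That kit does not mark strand, so overlapping antisense genes cannot be told apart. What HHT and SPEED stand for, whether Tregs were removed before lysis, the aligner and the sequencing depth in reads are not given in the sources used here.

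The authors deposited 1 table of raw counts per assay, with whole-number counts of reads per gene for 53465 gene identifiers. Per the submitters' processing notes the genome build was GRCm38, and HTSeq 0.4.1, Picard 1.134, FastQC 0.11.3 and SAMtools 1.2 were used. A further 16 columns of the RiboTag table match no sample and were not used. A pair of SPEED libraries carries the same title, mouse, HHT treatment and Input fraction, and the later library was left out of the fits, which used 44 SPEED libraries. The chi-square per degree of freedom between 2 libraries of a group was 1.81 or more in 123 pairs. That is above the 1 that repeat counts of 1 library would give, so no library was counted as a copy. The lowest value, 1.81, was between the HHT Pol libraries of mice 1 and 2.

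Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with its default minimum count of 10 and minimum total of 15, TMM scaling, and a robust quasi-likelihood fit of all groups of an assay together (common biological coefficient of variation 0.188 in RiboTag and 0.215 in SPEED). Tests were two-sided with Benjamini-Hochberg adjustment at 0.05, with no minimum fold. Ratios of fractions (IP over Input, Pol over SubPol) were tested as an interaction within the same fit. Standard errors are the log2 fold change over the square root of the F statistic, and intervals are at 95 percent. Mean CPM and SD are over libraries. Every library is scaled to its own total, so a change in total RNA, or in the share of all mRNA on polysomes, does not appear.

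Samples with the same mouse number came from the same mouse, per the labels, so the numbers pair the samples. Deviations from the group mean correlated within a mouse with a mean r of 0.201 in RiboTag (-0.085 to 0.523) and 0.08 in SPEED (-0.28 to 0.526). The means between mice were -0.05 and -0.026. They largely follow from the means within a mouse, since deviations sum to 0 in a group. In SPEED, 32 of 43 libraries with unrepeated titles correlated best with the mean profile of their own mouse. Stimulated Input of mouse 3 had r = -0.07 with mouse 3 and 0.427 with mouse 4. Stimulated Input of mouse 4 had 0.016 with mouse 4 and 0.165 with mouse 3. So the profiles do not bear out every mouse number in SPEED, and the pairing there rests on the labels. The mouse was left out of the main fits and added as a block in an alternative. The tests without the block are conservative for ratios, in which the shared part of a mouse cancels.

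Scores and gene sets per library used log2 CPM with a prior count of 2, and gene sets defined in the other assay or, for the polysome score, in untreated cells. Exact permutation tests, two-sided, were adjusted together over 21 tests. The 14 comparisons of groups, their tests and the planned processing alternatives were fixed before the data were examined. The culture as a block, mice 3 to 5 alone and the fit without the untreated SubPol library of mouse 3 were added afterwards. The scores and their alternatives, the alternatives of named genes, the gene sets and the checks with a mouse left out of the choice of genes were chosen after the data were examined. Named genes had to have an adjusted p under 0.05, a mean log2 CPM of at least 3 and the same sign in every mouse, with the 2 largest rises and the 2 largest falls in the RiboTag Input comparison of Tregs printed. The planned gene lists and terms on gene names need symbols, which the tables do not hold and which could not be matched here.

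The fits were tested on simulated counts with means, dispersions and library sizes of the real libraries, 200 genes changed per run and 5 runs per comparison. In RiboTag Input with Tregs against stimulated, 90.9% of well measured 2-fold changes and 57.0% of 1.5-fold changes were recovered, and 3.26% of calls were false. In SPEED Input the shares were 89.9% and 45.8%, with 3.96% false. Each simulated library was drawn on its own, with no part shared within a mouse or culture. When 10 percent of the activation change was taken back in simulated libraries, the activation score estimated 11.3% in Input and 11.5% in IP, and when none was taken back it gave -0.168% and 0.0153%.

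DESeq2 1.42.0, its size factors in edgeR, other filters, the mouse or the culture as a block, only the groups compared, each mouse left out and, for SPEED, Pol over Input were tried as alternatives. The mitochondrial, gene list and Treg marker alternatives were not run, for want of gene names, and the planned depth minimum removed no library, the shallowest holding 1566501 counts.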

Results

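The data were gene-level read counts from CD4 effector T cells of mouse spleen and lymph nodes, cultured with or without regulatory T cells (Tregs), the T cells that restrain the activation of other T cells. The study asked, by its title, how Tregs act on the control of translation during CD4 T cell activation, and 2 assays of ribosome association were used. In the RiboTag assay the effector cells came from 5 mice in which Cd4-driven Cre recombinase switches on a tagged copy of the ribosomal protein Rpl22. The RNA bound to tagged ribosomes (IP) was sequenced next to the RNA of the same culture before the precipitation (Input). Each of the 5 mice gave a culture rested with IL7, a culture stimulated with anti-CD3/CD28 beads and a stimulated culture with Tregs, 30 libraries in all. In the SPEED assay, cells of 4 other mice were fractionated on sucrose, and Input, polysomal RNA (Pol) and subpolysomal RNA (SubPol) were sequenced from untreated, stimulated, stimulated with Tregs and stimulated plus HHT (10 min) cultures. These were 45 libraries, with no HHT culture from mouse 4. RiboTag libraries held 1658481 to 2824875 gene counts, and SPEED libraries 1566501 to 4621104. After the filter on low counts, 10751 genes were tested in RiboTag and 12428 in SPEED.

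Stimulation changed the RNA level of 63.3% of the tested genes in RiboTag Input and 54.4% in SPEED Input. In RiboTag Input, 3435 genes were higher and 3375 lower than in IL7-rested cells (n = 5 mice per group), and 1710 and 1490 of them changed at least 2-fold. In the RNA bound to tagged ribosomes, 3615 genes were higher and 3341 lower. In SPEED Input, 3468 genes were higher and 3290 lower than in untreated cells (n = 4 mice per group). The genes that rose and the genes that fell were largely shared between the assays: 2467 genes were higher in both, where independent lists would share 1014, and 2206 were lower in both, where independent lists would share 960.6. In opposite directions, 169 genes passed the test in both assays. Across the 10690 genes tested in both, which are not independent replicates, the log2 fold changes correlated with r = 0.768 (Spearman's rho 0.756). All counts are of genes with a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, two-sided.

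The fractions of stimulated cells differed in which genes they held. In SPEED, 2930 genes were higher and 2712 lower in Pol than in SubPol (n = 4 mice), 986 and 1230 of them at least 2-fold. In RiboTag, 22 genes were higher and 83 lower in IP than in Input (n = 5 mice), with 250 genes past the test when the mouse was a block in the fit (92 higher, 158 lower). With the culture, which IP and Input share, as a block it was 849 genes, 466 higher and 383 lower, so the balance of directions depended on the fit. The count was 50, 62, 35 and 47 without mouse 2, 3, 4 or 5. Genes that favoured polysomes in SPEED also lay towards the tagged ribosomes. Of the 1012 genes at least 2-fold lower in Pol than in SubPol, 50 were lower in IP than in Input and 0 higher, and their median log2 change was -0.21. Of the 944 genes at least 2-fold higher in Pol, 10 were higher in IP and 0 lower, with a median of 0.17. The log2 ratios of the 2 assays correlated across 10690 genes with r = 0.379. The SD across well measured genes (mean log2 CPM of at least 5) of the log2 ratio was 0.27 for IP over Input and 0.71 for Pol over SubPol. These ratios are unlike, since Input includes the RNA that is precipitated, while Pol and SubPol are separate fractions. So the 2 SDs do not tell which method separates genes more.

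Stimulation also moved genes between SubPol and Pol. In SPEED, 194 genes rose and 129 fell in Pol over SubPol against untreated cells (n = 4 mice per group, interaction in one edgeR fit), and 28 and 58 of them moved at least 2-fold. Without the untreated SubPol library of mouse 3, which had 12851 genes detected against 13556 to 13735 in the other 3, 296 rose and 80 fell. With the mouse as a block the count was 556 genes, with the culture as a block 710 (400 higher, 310 lower), and with Pol set over Input in place of SubPol it was 1. Without mouse 1, 2, 3 or 4 the count was 62, 106, 138 and 168. In RiboTag, 1 gene rose and 2 fell in IP over Input after stimulation (0 without mouse 2 or 5). With the culture as a block 12 rose and 7 fell, and with mice 3 to 5 alone 5 rose and 4 fell. In the fit without a block, 604 genes had an unadjusted p under 0.05 where chance gives 537.6. Across the 10690 genes tested in both assays, the changes of the 2 ratios on stimulation correlated with r = 0.007 (rho 0.081). Of the 317 of these genes past the test in SPEED, 214 had the same sign in RiboTag, and 1 passed in both. The genes that moved in SPEED had a mean difference, risen minus fallen, in IP over Input of 0.26 ± 0.07 (SD, n = 5) in stimulated and 0.11 ± 0.15 (SD, n = 5) in rested cells of the RiboTag assay, a difference that did not pass (exact permutation p = 0.0952, two-sided, adjusted p = 0.154 over 21 such tests). This depended on rested mouse 2, at 0.375 where the other rested mice had at most 0.11. Without mouse 2 the difference was 0.21 (exact permutation p = 0.0286, unadjusted, the smallest that 4 against 4 can give). Each library was scaled to its own total, so a shift of all mRNA between SubPol and Pol cannot be measured from these counts.

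With Tregs, genes moved mostly against their direction on stimulation. In RiboTag Input, 297 genes were higher and 190 lower with Tregs than without (n = 5 mice per group), and in IP 371 were higher and 241 lower. Of the 1450 genes that stimulation had lowered at least 2-fold in the other assay, 132 were higher and 19 lower with Tregs in RiboTag Input, with a median log2 change of 0.26. Of the 1552 genes that stimulation had raised at least 2-fold, 67 were lower and 21 higher, with a median of -0.13. Among the 379 genes past the test for both stimulation in SPEED and Tregs in RiboTag Input, 322 (85.0%) moved in opposite directions, and for RiboTag IP it was 418 of 486 (86.0%). In SPEED Input, 57 genes were higher and 16 lower with Tregs (n = 4 mice per group). Of the 59 that had also passed for stimulation in RiboTag, 48 (81.4%) moved in opposite directions. This came from genes that stimulation had lowered, of which 41 were higher and 3 lower with Tregs. Of those it had raised, 7 were lower and 8 higher, so these calls showed no reversal. The 1691 genes raised at least 2-fold in RiboTag had a median log2 change of -0.12 with Tregs in SPEED Input. Taking stimulation and Tregs from separate assays keeps these relations free of shared control libraries. With the mouse as a block, the counts were 843 genes in RiboTag Input, 1077 in IP and 149 in SPEED Input. Without mouse 1, 3, 4 or 5, RiboTag Input gave 289, 192, 278 and 216 genes, and without mouse 3 or 5 the IP gave 280 and 221. The SPEED Input count fell from 73 to 8, 6, 14 and 41 genes with mouse 1, 2, 3 or 4 left out.

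The change with Tregs ran against the change on stimulation. Over the genes that stimulation changed at least 2-fold in the other assay, it was 10.2% to 12.5% of that change in size. Across all 10690 genes tested in both assays, the slope on the Input change with stimulation in the other assay was smaller. It was -0.059 for Tregs in RiboTag Input (r = -0.219), -0.064 in RiboTag IP (r = -0.223) and -0.071 in SPEED Input (r = -0.232). An activation score was taken for each library as the mean log2 CPM of the genes raised at least 2-fold by stimulation in the other assay minus that of the genes lowered at least 2-fold. Stimulation raised it in RiboTag Input from -2.31 ± 0.27 to 0.73 ± 0.07 (SD, n = 5), and with Tregs it was 0.38 ± 0.14 (SD, n = 5), lower in 5 of 5 mice. The IL7-rested Input libraries of mice 1 and 2 stood apart at -1.99 and -2.06, against -2.56 to -2.48 in mice 3 to 5, and with mice 3 to 5 alone stimulation changed 6673 genes in Input and Tregs 700. The difference with Tregs was -0.34 in Input and -0.36 in IP (exact permutation p = 0.00794 for each, two-sided, the smallest that 5 against 5 can give, adjusted p = 0.0417). That test exchanges libraries across mice. Paired by mouse, an exact sign-flip test gave p = 0.0625 for each, the smallest that 5 pairs can give, so that test cannot go under 0.05 here. The differences were 11.3% and 11.4% of the activation change, in a score chosen after the data were examined. In SPEED the differences were -0.39 in Input (p = 0.0571), -0.32 in Pol (p = 0.0857) and -0.37 in SubPol (p = 0.0286, exact permutation tests, n = 4 per group), lower in 4 of 4 mice for each fraction. With adjustment over 21 tests these were 0.109, 0.15 and 0.06, so none of the 3 passed. They were 12.5%, 10.2% and 12.2% of the activation change.

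**Figure D1:**
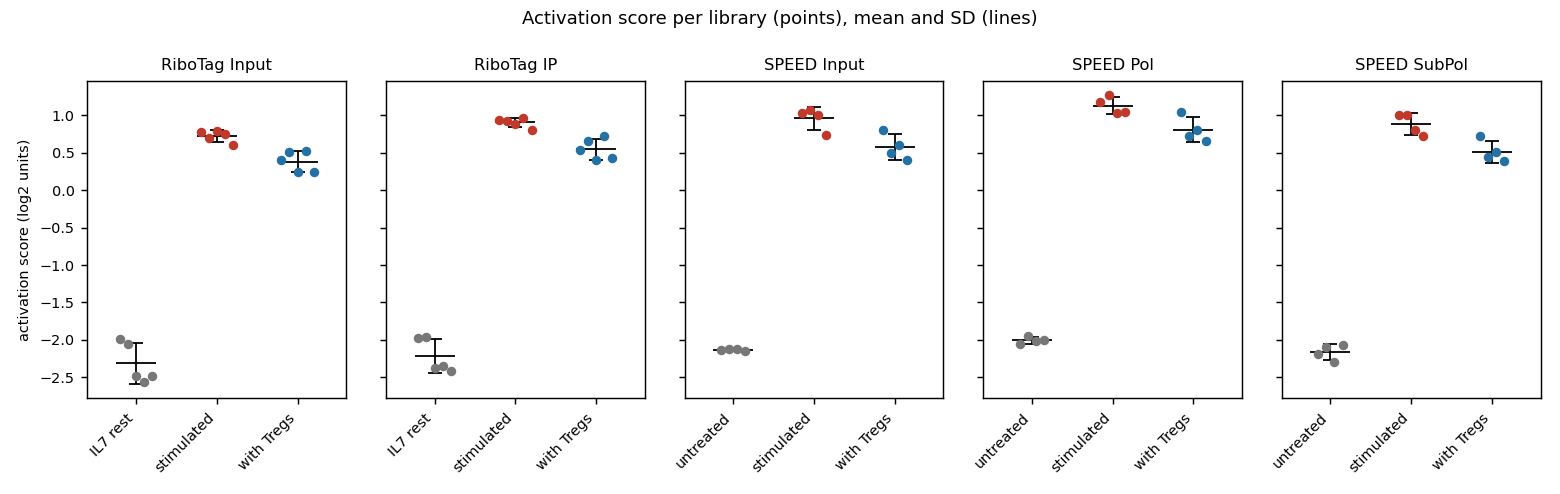
Activation score (mean log2 CPM of genes raised minus genes lowered by stimulation in the other assay, in log2 units) for each library, in 5 panels of assay and fraction; points are mice, black lines the mean and SD. With Tregs the mean lay 0.32 to 0.39 below that of stimulated cells in every panel, against a rise of 3.04 to 3.13 on stimulation.

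The 2 assays gave partly the same genes for the effect of Tregs on Input. Both had 18 genes higher, where independent lists would share 1.58, and 2 lower, where they would share 0.275, and 1 gene passed in opposite directions. Of the 481 RiboTag genes past the test and tested in SPEED, 417 had the same sign in SPEED. Across 10690 genes r was 0.272 and rho 0.418. Among genes with a mean log2 CPM of at least 5 in both assays, r was 0.539.

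Genes are given by the identifiers in the files, which do not pair them with names, and the planned gene lists could not be tested for the same reason. Of the 487 genes past the test in RiboTag Input, 441 met the rule for named genes apart from its terms on names (268 higher, 173 lower), and those with the largest changes follow. ENSMUSG00000046971 rose from 4.21 ± 2.13 CPM in stimulated cells to 25.4 ± 3.93 CPM with Tregs (SD, n = 5), a log2 fold change of 2.53 (SE 0.56, edgeR adjusted p = 0.00598). In IP it rose by 2.23 (adjusted p = 0.0183), a call lost without mouse 1 (adjusted p = 0.0909) or mouse 4 (adjusted p = 0.0665), with edgeR adjusted p between 0.00432 and 0.0909 over all alternatives. In SPEED Input its change was 0.16 (adjusted p = 0.94). ENSMUSG00000047415 rose from 13.7 ± 5.00 to 75.3 ± 9.07 CPM (SD, n = 5; log2 fold change 2.47, SE 0.27, adjusted p = 5.62e-07), by 1.93 in IP, and by 1.46 in SPEED Input, where it did not pass (adjusted p = 0.08, edgeR). There it passed with only the groups compared in the fit (edgeR adjusted p = 0.0192) and without the untreated SubPol library of mouse 3 (adjusted p = 0.017), and not in the other alternatives. ENSMUSG00000028527 fell from 35.5 ± 17.8 to 4.21 ± 2.29 CPM in Input (SD, n = 5; log2 fold change -3.08, SE 0.48, edgeR adjusted p = 0.00019), and its change in SPEED Input was -1.14 (adjusted p = 0.359). ENSMUSG00000037820 fell from 31.4 ± 12.4 to 3.54 ± 5.22 CPM (SD, n = 5; log2 fold change -3.08, SE 0.62, edgeR adjusted p = 0.00372). The level with Tregs was 12.8 CPM in mouse 2 and 0.708 to 2.49 CPM in the other 4 mice, and without mouse 2 the log2 fold change was -4.42 (edgeR adjusted p = 0.000419). ENSMUSG00000037820 did not pass the filter on low counts in SPEED and was not tested there. Both of the genes that fell had 0 counts in all 5 IL7-rested Input libraries.

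The genes that changed with Tregs changed alike in Input and IP, and no gene passed the test for their ratio. Of the 487 genes past the test in RiboTag Input, 485 had the same sign in IP, and 201 higher and 128 lower genes passed in both. In IP over Input, 0 of 10751 genes passed with Tregs in edgeR (125 at an unadjusted p under 0.05, where chance gives 537.6), and 0 in DESeq2 (198 at p under 0.05). In Pol over SubPol, 0 of 12428 genes passed in edgeR (328 at p under 0.05, where chance gives 621.4), and 0 in DESeq2 (344 at p under 0.05). In simulated counts with the spread of these libraries, the same test recovered 72.4% of well measured genes with a 2-fold change in IP over Input and 60.6% in Pol over SubPol, but 24.2% and 12% of those with a 1.5-fold change. The simulation drew each library on its own, without the part that fractions of a culture share. So these shares may not hold for the real ratios. The estimated intervals excluded a 2-fold change for 95.4% and 88.2% of well measured genes. The activation genes changed by -0.01 in IP over Input and by 0.05 in Pol over SubPol with Tregs (exact permutation p = 0.627, n = 5, and p = 0.171, n = 4).

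HHT, by contrast with Tregs, changed the distribution of genes between Pol and SubPol widely. With HHT, 1284 genes rose and 1576 fell in Pol over SubPol against stimulated cells (n = 3 against 4 mice), 1664 in all without mouse 1. Of the 833 genes at least 2-fold higher in Pol than in SubPol of untreated cells, 309 fell and 3 rose (median log2 change -0.73), and of the 733 genes at least 2-fold lower, 235 rose and 1 fell (median 0.89). A polysome score, the mean log2 ratio of Pol over SubPol of the first set minus that of the second, was 2.10 ± 0.13 in stimulated cells (SD, n = 4), 2.10 ± 0.06 with Tregs (SD, n = 4) and 0.66 ± 0.20 with HHT (SD, n = 3). It was lower with HHT in 3 of 3 mice, by a mean of -1.44 between groups (exact permutation p = 0.0286, two-sided, adjusted p = 0.06 over 21 tests), and moved by -0.0038 with Tregs (exact permutation p = 1). The SD of log2 Pol over SubPol across genes was 1.00 ± 0.09 in stimulated cells, 1.00 ± 0.06 with Tregs and 0.76 ± 0.13 with HHT (difference with HHT -0.24, exact permutation p = 0.0286, n = 3 against 4, adjusted p = 0.06). In Input, HHT raised 13 genes and lowered 0 (n = 2 against 4 libraries, edgeR). Without mouse 1 it was 2 genes and without mouse 3 it was 9, but each of these leaves 1 HHT library, whose spread is taken from the other groups. In the full comparison, 1025 genes had an unadjusted p under 0.05 where chance gives 621.4, and DESeq2 called 29.

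**Figure D2:**
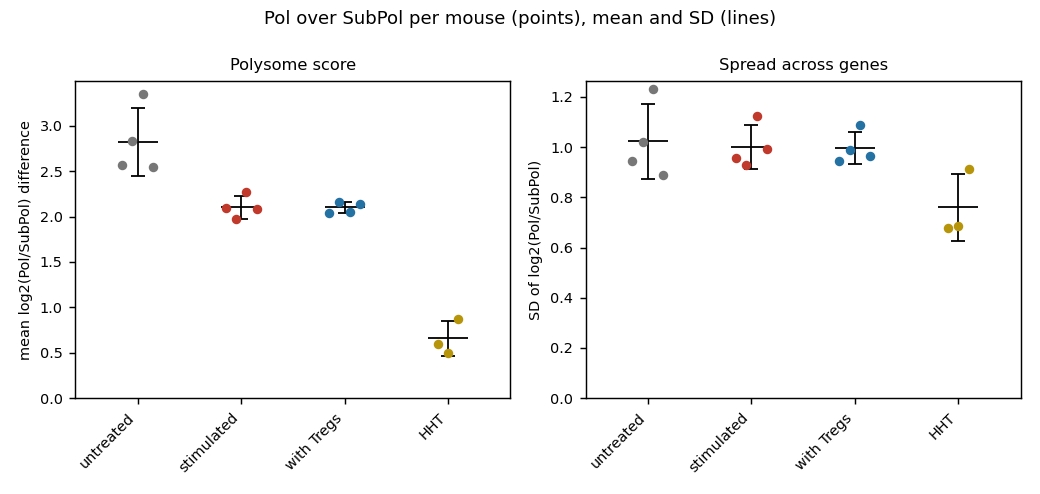
Polysome score (left, in log2 units) and SD of log2 Pol over SubPol across genes (right) for each mouse of the SPEED assay; points are mice, black lines the mean and SD. The HHT cultures had the lowest mean in both panels, 0.66 and 0.76, and the Treg cultures lay at 2.10 and 1.00, as the stimulated cultures did. The genes of the polysome score were chosen in the untreated libraries, so the untreated points in the left panel are high by construction.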

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

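The tests of explanations below, and their expected outcomes, were written after the values they measure had been seen, the counts over other splits of the samples included, except those with the culture as a block.

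The change with Tregs in Input differed between the assays in 16 of 11232 genes (edgeR, interaction over 27 Input libraries, adjusted p under 0.05; 716 at an unadjusted p under 0.05, where chance gives 561.6). In 12 of them it was lower in RiboTag and in 4 higher. Of 100 regroupings of the cultures within each assay, 4 gave as many genes, the real one included, and the highest of the others gave 388. That regrouping kept all 4 SPEED cultures with Tregs together and mixed those of RiboTag. In RiboTag it put both cultures of mice 1 and 4 on the same side, so it also parted RiboTag mice. Whether the grouping by Tregs in SPEED or the parting of RiboTag mice gave the 388 genes was not tested. Another kept the grouping of RiboTag and gave 26. Such regroupings leave the effect of 1 assay in the difference. A regrouping that exchanged 1 culture with and 1 without Tregs in each assay, and so largely kept the grouping by Tregs, gave 55. So this count does not decide whether the 16 genes are due to chance. Mouse strain and assay differ together here and cannot be told apart.

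Genes that rose with Tregs in Input rose as far in the IP. In a mouse left out of the choice of genes, the median change was 0.67 ± 0.16 in Input and 0.65 ± 0.14 in IP (SD, n = 5 mice), and the ratio of the changes was 0.971 on average, between 0.885 and 1.08. RNA of untagged cells that is in Input and not on tagged ribosomes would have raised Input more. The ratio stayed above 0.5 in 5 of 5 mice, which speaks for the median gene and not for each gene. The 2 named genes that rose had smaller changes in IP. These were 2.23 against 2.53 in Input for ENSMUSG00000046971 and 1.93 against 2.47 for ENSMUSG00000047415. Neither passed the test for the ratio. Unselective carry-over of Input RNA into the precipitate would leave no abundant gene far below its Input level, and 10 abundant genes, each past the test, had a log2 change below -2, with a median of 6.61% of their Input level left. The 10 genes, of 7205 well measured, have no names here. So they speak only against carry-over of every transcript alike, and carry-over that leaves such genes out remains open. Ribosomes of Tregs that stick to the precipitate selectively, and a real change in the effector cells, also remain open. No precipitate from untagged cells was analysed here. For single genes, RNA of untagged cells in Input also remains open.

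A pair of libraries carries the title and the mouse of the same HHT Input sample. The later one correlated better with the mean profile of mouse 1 than of mouse 2, by 0.125, which lies below the range of the libraries of mouse 1 (0.149 to 0.435) and inside that of mouse 2 (-0.377 to 0.164). The earlier one, kept in the fits, had 0.084, which lies outside and inside the same ranges. So the profiles leave open which mouse either came from, and including the later one raised the Input HHT count from 13 to 32 genes.

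Some libraries lay far from the others of their group. In the activation ratio score of IP over Input, IL7-rested mouse 2 had 0.375 where the next value was 0.11. For ENSMUSG00000046971 they were, in CPM, 18.6 in the RiboTag Input with Tregs of mouse 3, 6.90 in the stimulated Pol of mouse 3, 18.3 in the SubPol with Tregs of mouse 3, and 0.880 in the untreated Pol of mouse 2. For ENSMUSG00000047415 they were 38.5 CPM in the IL7-rested Input of mouse 3 and 81.0 CPM in the IP with Tregs of mouse 3. For ENSMUSG00000028527 they were 0.431 CPM in the IL7-rested IP of mouse 4 and 6.24 CPM in the untreated SubPol of mouse 2, and for ENSMUSG00000037820 it was 12.8 CPM in the RiboTag Input with Tregs of mouse 2. In all, 10 values stood out in 99 groups of 4 or 5 samples, where chance gives about 4.95 if values are normally distributed. That figure does not hold for groups near 0 counts, such as those of the 0.880 and 0.431 CPM, whose nearest values were 0. So the 2 numbers do not show an excess.

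Whether other groupings of the same cultures gave as many genes was counted for the group comparisons with at least 3 mice per group. In RiboTag, 1 of 100 splits, the real one, gave as many genes for stimulation in Input (6810, highest other 1506) and in IP (6956, highest other 1437), for Tregs in Input (487, highest other 104) and for IP against Input (105, highest other 32). For Tregs in IP it was 2 of 100: the real split gave 612 genes, and a split that exchanged 1 culture with and 1 without Tregs gave 675. Of the other splits that set the cultures of all 5 mice apart, as the real one does, the highest gave 0. In SPEED, 1 of 35 splits, the real one, gave as many for stimulation in Input (6758, highest other 1), for Tregs in Input (73, highest other 0), for HHT in Pol over SubPol (2860, highest other 1050) and for Pol against SubPol (5642, highest other 1406). Grouping at random across mice can be excluded for these at a share under 0.05. Splits that keep the pairing by mouse are too few to reach such a share. In SPEED there were 7 of them besides the real one.

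For stimulation in IP over Input (3, highest other 0, 1 of 100 splits) and in Pol over SubPol (323, highest other 0, 1 of 35 splits) this count decides nothing. The other splits mix stimulated and unstimulated cultures, which raised the common biological coefficient of variation from 0.188 to at least 0.353 in RiboTag and from 0.215 to at least 0.398 in SPEED, and a count of 0 was to be looked for. With the culture as a block, a count added after the data were examined, the change in RNA level stays in the culture terms, and the coefficient was 0.121 in the real split and 0.121 to 0.128 in the others in RiboTag, and 0.183 and 0.19 to 0.196 in SPEED. There 1 of 60 splits, the real one, gave as many genes in IP over Input (19, highest other 1) and 1 of 35 in Pol over SubPol (710, highest other 3). So grouping at random across mice can be excluded for the counts of this fit. Splits that keep the pairing by mouse are again too few for a share under 0.05.

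For Tregs in IP over Input and in Pol over SubPol the real count was 0, so all 100 and 35 splits gave as many (highest other 0 and 1 among these splits).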

How the results depend on the processing

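The alternatives of scores and named genes, the block by culture, mice 3 to 5 alone and the untreated SubPol library of mouse 3 left out were chosen after seeing the data. The counts of 0 for Tregs in both ratios of fractions held in all alternatives run. The cause of the changes below was not tested. With the mouse as a block (replicate block), 843 genes passed for Tregs in RiboTag Input, 1077 in IP, 149 in SPEED Input, 250 for IP against Input and 556 for stimulation in Pol over SubPol, and no other count moved over 1.5 times. With the culture as a block, these were 849 for IP against Input, 710 for stimulation in Pol over SubPol and 19 in IP over Input (9 with mice 3 to 5 alone). With no filter, Tregs gave 399 in IP and 47 in SPEED Input, and stimulation 176 in Pol over SubPol. With only the groups compared, Tregs gave 948 in RiboTag Input and 166 in SPEED Input, and stimulation 115 in Pol over SubPol. DESeq2 gave 239 for IP against Input, 669 for stimulation in Pol over SubPol, 260 for Tregs in SPEED Input and 29 for HHT in Input. Pol over Input gave 1 gene for stimulation, and the second library of the repeated title 32 for HHT in Input.

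Leaving out each mouse gave 192 to 476 genes for Tregs in RiboTag Input, 221 to 445 in IP and 6 to 41 in SPEED Input. It gave 0 to 2 for stimulation in IP over Input, 35 to 90 for IP against Input, 62 to 168 for stimulation in Pol over SubPol, 1664 to 2418 for HHT in Pol over SubPol and 2 to 14 in Input. With a mouse left out, 3 against 3 SPEED mice cannot go under p = 0.1 in an exact permutation test. There the activation score on stimulation was 3.06 to 3.19 in Input, 3.09 to 3.18 in Pol and 2.99 to 3.15 in SubPol, and with Tregs -0.399 to -0.307 in SubPol. The polysome score with HHT was -1.52 to -1.34 and the spread -0.268 to -0.208. The agreement on stimulation was 0.746 to 0.765.

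Among genes with a mean log2 CPM of at least 5 in both assays, agreement rose to 0.847 for stimulation in Input, 0.155 in the ratios and 0.539 for Tregs in Input. The correlation of Tregs with stimulation was -0.413, -0.446 and, for IP, -0.378. Over all genes tested in both assays, the IP value was -0.223, and -0.226 to -0.171 with a mouse left out. For ratios the correlation was 0.0534 and 0.00332 among the genes of log2 CPM at least 5. Over all genes, with a mouse left out, it ran from 0.0142 to 0.0379 and from 0.00271 to 0.0439. The difference in activation score in SPEED Input, with Tregs minus stimulated, was -0.442 (exact permutation p = 0.0286). The activation ratio score of IP over Input, IL7 rest minus stimulated, was -0.162 (exact permutation p = 0.0476). Neither p was adjusted over the 21 tests. In the main analysis this difference of the ratio score was -0.143, and it ran from -0.212 to -0.0941 there with a mouse left out.

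Some values that had not passed changed sign. The spread of untreated cells went to -0.116 by median absolute deviation (exact permutation p = 0.0286) and to -0.00494 with prior count 5, and from -0.000508 to 0.0593 with a mouse left out. With Tregs the spread ran from -0.025 to 0.0123 and the polysome score from -0.0858 to 0.0613, and in RiboTag at rest the latter ran from -0.00286 to 0.0405. The activation genes in IP over Input ran from -0.0294 to 0.00345, and to 0.00879 among genes of log2 CPM at least 5. ENSMUSG00000046971 in SPEED Input ran from -0.03 to 0.26.

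Not run, for want of gene names, were the alternatives without mitochondrial genes or Treg markers and those of gene lists. The depth minimum removed no library. At this depth, spread and number of mice, simulated 1.5-fold changes in ratios were mostly missed, and which of these limits most was not tested. The simulated libraries did not hold the part that fractions of a culture share, so the real ratios may differ.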

Other observations

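The tests in this part were chosen after the data were examined, apart from the planned comparison of IP with Input in stimulated cells, for which only the limit on expression was chosen afterwards.

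The between-mouse agreement of Pol over SubPol was lower with HHT than in stimulated cells, and overlapped that of untreated cells. The 6969 genes used had a mean over libraries of log2 CPM, with a prior count of 2, of at least 5. The well measured genes above are set by edgeR's average log2 CPM instead. The log2 ratio correlated between mice with r from 0.815 to 0.883 in stimulated cells and from 0.79 to 0.873 with Tregs. In untreated cells r was from 0.604 to 0.744, and with HHT from 0.482 to 0.611. The SD of the part of that ratio shared between mice was, in the same order, 0.69, 0.66, 0.60 and 0.33 on the log2 scale. In RiboTag, IP over Input correlated between mice with r from 0.366 to 0.603 in stimulated cells, and the shared SD was 0.24 in stimulated cells, 0.24 with Tregs and 0.27 in IL7-rested cells.

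A few abundant genes were low in the precipitate. Of 7205 well measured genes, 58 were lower and 22 higher in IP than in Input of stimulated cells (edgeR), the lowest with 2.05% of its Input level left and the highest at a log2 change of 0.65. With the culture as a block, 466 of all tested genes were higher and 383 lower, so the surplus of lower genes depended on the fit.

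A hypothesis was that Tregs shift genes between Pol and SubPol in the direction of HHT, to a smaller extent. The slope of the change with Tregs on the change with HHT, over 6969 genes, was above 0 in 4 of 4 mice, with a mean of 0.0452 ± 0.0218 (SD, n = 4) against 0.791 to 0.852 for HHT itself. An exact sign-flip test gave p = 0.125, the smallest that 4 mice allow, and slopes between stimulated cultures of different mice reached 0.107 in size. A small shift may exist, and these libraries cannot tell it from differences between cultures.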
